A study of Mus musculus with 20 samples.

How the data were processed

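Poly(A) RNA from melb-a cells, an immortal mouse melanoblast line, had been sequenced from stranded libraries. The 20 libraries fell into 5 groups of 4: parental cells that received no virus, cells with a lentiviral hairpin against luciferase (shLuciferase), cells with a scrambled hairpin (shScramble), and cells with either of the hairpins against the histone chaperone gene Hira (shHIRA I and shHIRA II). Per the labels' protocols, virus was left on the cells for 16 h with 8 µg/ml polybrene, infected cells were selected with 1 µg/ml puromycin, and the medium held 10% serum, 10 ng/ml SCF and 40 pM Fgf2. The design text calls the 4 libraries of a group independent replicates.

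Analysis began from the authors' gene tables, one of counts and one of TPM. Per the submitters' processing notes, bcl2fastq, kallisto and edgeR were used with genome build mm10. Their versions, the transcript annotation and the strand setting were not given in the sources used here. The deposited counts were estimated counts per gene and not whole numbers. In the 8630 genes compared, the ratio of a gene's count to its TPM was the same in every library up to 1 factor per library, to within 1e-06 on the log2 scale. The deposited counts therefore equal TPM times 1 length per gene, scaled to a total per library. Such values carry no counts of single transcripts, and a shift between long and short isoforms of a gene does not enter them. The deposited TPM values, which the authors scaled per library, were used for a second scaling and for exact tests of Hira. They summed to between 793366 and 864638 over the rows of a library, so other transcripts held the remainder up to a full library.

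Columns were assigned to samples by their names. Columns named as control without a hairpin were taken as parental, the sole group left over, and shHIRA columns with no numeral as shHIRA I, for the same reason. The tables held 29956 gene rows, of which 6990 were 0 in every library. Spreadsheet dates stood in place of 27 gene names, 2 of which were repeated; these rows kept their values and were not named. Symbols of 28161 rows matched GENCODE M21, the annotation of GRCm38 (mm10) used here for positions. Estimated counts were rounded to whole numbers before any count test. Library totals ran from 15.0 to 20.7 M counts (M, 1e6).

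The test of every comparison was edgeR's quasi-likelihood F test with TMM scaling, its default filter on low counts by group, and a group-means model over all 20 libraries, so that each gene had 1 estimate of its spread. The filter left 13541 genes. Benjamini-Hochberg adjusted p-values under 0.05 over all genes tested counted as calls. The contrasts were the mean of both shHIRA groups minus the mean of both control shRNA groups (HIRA knockdown), each shHIRA group minus that mean, shHIRA II minus shHIRA I, shScramble minus shLuciferase, and the mean of the control shRNA groups minus parental (transduction). A gene counted as changed with both hairpins against both controls when all 4 contrasts of a shHIRA group with a control shRNA group were called in 1 direction. Errors of log2 fold changes are standard errors from the fit, and levels are counts per 1e6 counts (CPM) or TPM as mean ± SD over 4 libraries. The 95% interval of the Hira ratio came from its log2 fold change and standard error. Single measures were compared by two-sided exact permutation tests of the difference of means, as a family of 16 tests with Benjamini-Hochberg adjusted values. Depth and 4 libraries a group limit what can be called, and of simulated 2-fold changes a part was missed.

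Gene lists, the model, the alternatives marked as planned and the rule for named genes were written before the data were examined. The 28 lists held 770 members, of which 764 had a row and 660 were tested (632 distinct genes). Each list was tested with limma's camera on voom values, with a preset correlation of 0.01 between genes and adjustment over the 28 lists, and again with an estimated correlation and with fry. Camera compares a list with all other genes; fry asks whether its members move, on balance, in 1 direction. Counts of members that rose or fell are given over all genes tested and adjusted over the list alone. The lists were: HIRA complex and H3.3; genes next to Hira; melanocyte regulators; pigment synthesis and melanosome; neural crest and melanocyte stem cell; S phase; G2 and M phase. Histones were listed as replication-dependent and replication-independent. Further lists covered p53 targets, senescence and SASP, interferon response, extracellular matrix and mesenchyme, Schwann cell and glia, neuron, keratinocyte and epithelium, leukocyte, oxidative phosphorylation, cytosolic ribosomal proteins and cholesterol synthesis. The remaining lists were amino acid stress and unfolded protein response, MAPK output and immediate early, Wnt targets, TGF-beta and BMP targets, Notch targets, glycolysis and hypoxia, NRF2 targets, and lysosome.

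Named genes followed a rule. For the knockdown these were Hira and the 12 largest rises and 12 largest falls among genes called in all 4 contrasts of hairpin and control in 1 direction, with a mean of at least 5 CPM over the 16 transduced libraries. Predicted genes (Gm numbers), Rik clones, pseudogenes and rows without a symbol were left out. For each other contrast the 5 largest rises and 5 largest falls were named, with at least 5 CPM on average over the libraries of the groups compared. From each list up to 4 members with the smallest p were named, and every called member where a list had 5 or fewer. Exceptions, each named after its values were seen, were Gm28539 and the 4 rows called between the control shRNAs under other settings.

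Positions of the 52 named genes came from GENCODE M21. Sequence shared between genes was measured as the percentage of a gene's 31-mers found in transcripts of any other gene; 9 of the 52 shared over 20% and are reported as uncertain, as are antisense overlaps, because the counting's use of strand was not given. Shares of mitochondrial mRNA are the 13 mitochondrial rows as a percentage of a library's counts.

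Each procedure was tested on simulated counts with the real means and library sizes and a known set of changed genes. Over 13337 simulated genes the knockdown contrast recovered 62% of 2-fold and 93% of 4-fold changes, with 2.99% false calls among 167. For shHIRA I the shares were 51% and 90%, and for shHIRA II 52% and 90%. The rule of both hairpins against both controls recovered 23% and 77%. Between the control shRNAs, where nothing was changed, it made 0 calls. DESeq2 recovered 74% and 95% of the knockdown changes, with 13.9% false calls, and limma on log2(TPM + 1) 63% and 91%. A simulated list shifted by a fold of 1.5 was called by camera with either correlation and by fry, and of 25 unchanged lists 0 were. Simulated genes varied independently, so this does not test camera on genes that vary together. In the real data camera with its preset correlation called 6 of 28 lists between the control hairpins.

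To compare the hairpins, log2 fold changes were correlated across genes against the same 8 control libraries and against split controls, beside 20 simulated sets of unchanged groups. Alternatives chosen before the data were seen were DESeq2, RLE factors, limma on log2(TPM + 1) and log2(TPM + 0.1), no filter on low counts, a stricter filter (1 CPM in 4 libraries and a mean of 5 CPM), a fold threshold of 1.5, only the groups compared, a 2-group fit, each control alone, parental cells as control, the replicate number as a block and leaving out each library. After the data were seen, 3 more were added: the share of mitochondrial mRNA as a covariate, the fits without the 2 libraries lowest in that share, and the summed counts of Hira and Gm28539. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. No pair of libraries within a group was a duplicate: over 30 pairs, chi-square per degree of freedom was at least 11.6 for genes with at least 10 counts in sum. Reads were not analysed here, and neither were hairpin sequences, which were not given in the sources used here, so off-target matches were not searched.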

Results

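Transcript levels were measured by poly(A) RNA-seq in melb-a cells, a mouse melanoblast line kept in culture as unpigmented or weakly pigmented precursors of melanocytes. HIRA is a chaperone that deposits the histone variant H3.3 outside of DNA replication, and the design asks what its loss does to the transcriptome of these cells. Parental cells, cells with either of 2 control hairpins (shLuciferase, shScramble) and cells with either of 2 hairpins against Hira (shHIRA I, shHIRA II) gave 4 libraries each, 20 in all. Mean depth was 19.3 ± 1.52 M counts (M, 1e6) in parental cells (SD, n = 4) and 18.8 ± 1.78 M with shLuciferase. It was 18.4 ± 1.28 M with shScramble, 17.5 ± 2.02 M with shHIRA I and 16.8 ± 0.783 M in the libraries labelled shHIRA II. Of 29956 genes, 13541 had enough counts to be tested.

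Hira itself, on chromosome 16 (18877037 to 18970309, plus strand, GRCm38, protein-coding, ENSMUSG00000022702.16), was clearly lower with shHIRA I only. Its level was 36.8 ± 8.46 CPM with shHIRA I and 66.8 ± 4.12 CPM in the libraries labelled shHIRA II (SD, n = 4 each). It was 78.2 ± 12.4 CPM with shLuciferase, 74.1 ± 7.80 CPM with shScramble and 88.1 ± 8.57 CPM in parental cells. Single libraries ran from 26.6 to 45.4 CPM with shHIRA I, from 63.2 to 70.9 CPM with shHIRA II, from 63.7 to 89.8 CPM with shLuciferase, from 64.4 to 81.7 CPM with shScramble and from 81.9 to 101 CPM in parental cells. Against the control shRNA libraries, Hira with shHIRA I stood at 48.3% (95% interval 39.3 to 59.4%; log2 fold change −1.05, SE 0.14, adjusted p = 5.15e-05). In the libraries labelled shHIRA II it stood at 87.8% (interval 72.0 to 107%; log2 fold change −0.19, SE 0.14, adjusted p = 0.306), so a fall was not detectable there, while the interval leaves room for one of moderate size. The hairpins differed by 0.86 on the log2 scale (SE 0.16, adjusted p = 0.00096), and pooled over both the level was 65.1% of control (log2 fold change −0.62, SE 0.11, adjusted p = 0.000428).

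TPM gave the same picture for each hairpin: 24.4 ± 5.85 with shHIRA I and 44.1 ± 7.14 in the libraries labelled shHIRA II, against a control mean of 47.3 (two-sided exact permutation p = 0.00202 and 0.501, adjusted 0.00646 and 0.501). For both hairpins together the TPM test gave a two-sided exact permutation p of 0.0246, which did not pass after adjustment (0.0561). Gm28539, a predicted gene that overlaps Hira on the same strand and was singled out after its values were seen, had an estimated count of 0 in all 8 shHIRA libraries and of 0 to 313 in the 12 others, 2 of which were at 0 (exact permutation p = 0.0014 for both hairpins against the control shRNA libraries, adjusted 0.00646). The adjustment does not cover that choice, so this p-value does not stand as support. Transcripts of other genes, Gm28539 foremost, share 43.1% of the 31-mers of Hira, so the split of reads between these genes is uncertain. With both genes summed, the log2 fold changes were −1.14 for shHIRA I and −0.28 for shHIRA II (adjusted p = 0.158). The pooled fall did not pass in a fit that counts differences between hairpins as spread (log2 fold change −0.53, adjusted p = 0.0511) or against a fold of 1.5 (adjusted p = 0.82). With the share of mitochondrial mRNA as a covariate, a fit chosen after the data were seen, the libraries labelled shHIRA II passed (−0.46, adjusted p = 0.0394). Because Hira was not measurably lower in these libraries under the planned test, each direction drawn from them belongs to the libraries labelled shHIRA II.

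Mitochondrial mRNA made up 4.19 ± 0.876% of counts in the libraries labelled shHIRA II and 5.70 ± 3.44% with shHIRA I. It made up 7.98 ± 1.51% with shLuciferase, 8.23 ± 1.06% with shScramble and 7.17 ± 1.40% in parental cells (SD, n = 4 each). The share was lower than in the control shRNA libraries for shHIRA II (two-sided exact permutation p = 0.00202, adjusted 0.00646) and for both hairpins together (p = 0.00575, adjusted 0.0153), and not for shHIRA I alone (p = 0.0788, adjusted 0.105). Replicate 3 of shHIRA I stood lowest of all libraries at 1.23%, followed by replicate 2 of shHIRA II at 2.88%. Within groups, 3258 of the 13541 genes followed this share.

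**Figure D1:**
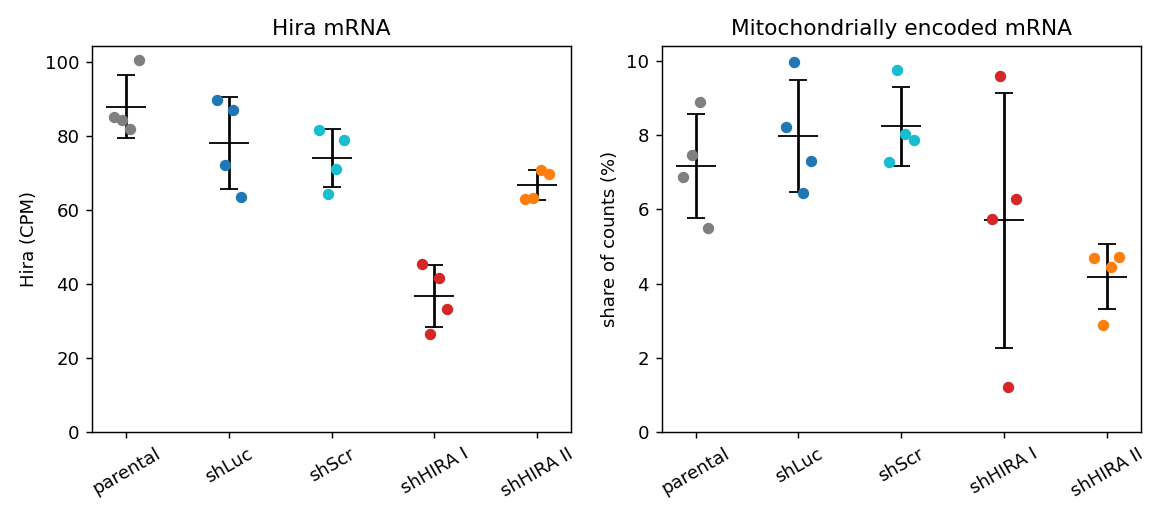
Hira in CPM and the share of mitochondrial mRNA in percent of counts, 1 point per library and a bar at the mean with its SD for each group of 4. Hira lies between 26.6 and 45.4 CPM with shHIRA I and at 63.2 CPM or above in the libraries of every other group, and the mitochondrial share is lowest in shHIRA I replicate 3 (1.23%).

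Pigment genes were the most clearly lowered group in the shHIRA libraries. The comparison of both shHIRA groups with both control shRNA groups asks which transcripts change with HIRA knockdown. It pools both hairpins, although only shHIRA I measurably lowered Hira. As shHIRA II minus shHIRA I, Tyr differed by −2.04, Pmel by −1.75 and the median of the pigment list by −0.49. Dct was not called as different. For Tyr and Pmel the larger fall thus did not go with the lower Hira. Of 23 measured genes of pigment synthesis and the melanosome, 15 fell and 1 rose (median log2 fold change −1.28, camera adjusted p = 7.45e-10, adjusted p = 0.151 with an estimated correlation). Tyr, the rate-limiting enzyme of melanin synthesis (chromosome 7, 87424771 to 87493512, minus strand, GRCm38), fell 13.5-fold, from 187 ± 109 and 196 ± 77.5 CPM with shLuciferase and shScramble to 28.8 ± 18.2 CPM with shHIRA I and 6.96 ± 2.82 CPM in the libraries labelled shHIRA II (SD, n = 4 each; log2 fold change −3.75, SE 0.37, adjusted p = 1.33e-06). Dct, dopachrome tautomerase (chromosome 14, 118012790 to 118052244, minus strand), fell 6.12-fold (−2.61, SE 0.23, adjusted p = 4.20e-07) and Pmel, the fibril protein of the melanosome (chromosome 10, 128704195 to 128720238, plus strand), 5.76-fold (−2.53, SE 0.26, adjusted p = 1.81e-06). Rab27a, which tethers melanosomes to their motor (−1.97), Slc24a5, a melanosomal cation exchanger (−2.26), and Tspan10 (−2.17) also fell. Tyr itself stood at 34.3 ± 3.21 CPM in parental cells, so against these its fall was smaller (−1.28, adjusted p = 0.0263), while the list's median against parental cells was −0.96 with 15 members lower and 2 higher.

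Melanocyte regulators fell in part: 7 of 16 fell and 2 rose (9 and 3 adjusted over the list alone, median −0.51, camera adjusted p = 0.0130, adjusted p = 0.435 with an estimated correlation). The list was called in the libraries labelled shHIRA II (camera adjusted p = 0.00333, adjusted p = 0.413 with an estimated correlation) and not with shHIRA I (0.238). Kit, the receptor for the SCF in the medium (chromosome 5, 75574916 to 75656722, plus strand), fell by 1.73 on the log2 scale (SE 0.24, adjusted p = 3.40e-05), Mitf, the transcription factor at the head of the pigment program (chromosome 6, 97807052 to 98021349, plus strand), by 1.21 (SE 0.17, adjusted p = 3.87e-05), Irf4 by 1.47 and Bhlhe40 by 1.21. With the share of mitochondrial mRNA as a covariate this list was no longer called (median −0.13, adjusted p = 0.291), whereas 13 pigment genes still fell (median −1.09). Of 16 measured neural crest and melanocyte stem cell genes, 8 rose and 7 fell (8 and 8 adjusted over the list alone). Aldh1a1 (3.34) and the progenitor filament gene Nes (0.80) rose, and Foxd3 (−1.19) and Ets1 (−0.92), transcription factors of the neural crest, fell. The list's median was −0.01, its mean 0.22 and camera's direction up (adjusted p = 0.889), and the median's sign turned with RLE or DESeq2 factors and with TPM.

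**Figure D2:**
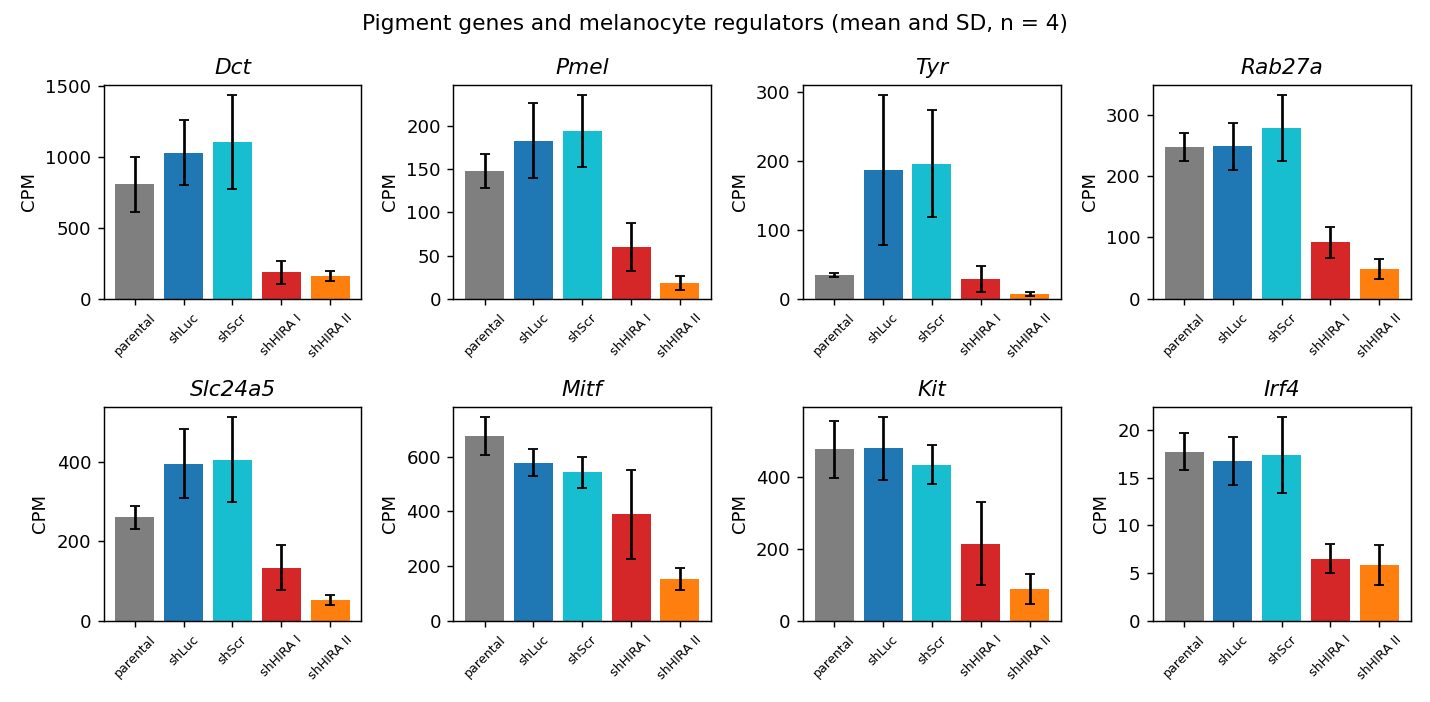
Levels in CPM of the pigment genes Dct, Pmel, Tyr, Rab27a and Slc24a5 and the regulators Mitf, Kit and Irf4. Bars show the mean and SD of each group of 4 libraries on a linear scale. Tyr lies at 34.3 ± 3.21 CPM in parental cells, near 187 and 196 CPM with the control hairpins, and at 28.8 and 6.96 CPM on average with shHIRA I and in the libraries labelled shHIRA II.

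Cholesterol synthesis and lysosomal genes were lower as well, by less with shHIRA I than in the libraries labelled shHIRA II. In that order the medians were −0.26 and −0.87 for cholesterol synthesis and −0.20 and −0.59 for lysosomal genes. None of the 25 cholesterol synthesis genes rose and 18 fell, the same counts as adjusted over the list alone (median −0.49, camera adjusted p = 9.84e-08, adjusted p = 0.276 with an estimated correlation). Among them were Insig1 (−1.25), a sterol sensor, and Mvd (−0.84). Of 29 lysosomal genes 15 fell and 1 rose (15 and 2 adjusted over the list alone, median −0.38, camera adjusted p = 0.000182, adjusted p = 0.435 with an estimated correlation). Among them were Psap (−0.93), Lamp1 (−0.73), Tpp1 (−0.89) and Mcoln1 (−0.54). Against parental cells the list was not called (adjusted p = 0.366). Interferon response genes were lower in 12 of 48 and higher in none (9 adjusted over the list alone, median −0.34, camera adjusted p = 0.00284, fry adjusted p = 0.193, adjusted p = 0.864 with an estimated correlation). The median was −0.80 with shHIRA I and 0.07 in the libraries labelled shHIRA II, where the list was not called (camera adjusted p = 0.759). In the latter the median was −0.71 with 6 falls with the mitochondrial covariate and −0.10 without the 2 libraries of lowest share. Among the falls were B2m (−0.98), Cmpk2 (−1.48) and Parp14 (−0.94). Their median lay 1.74 above the parental libraries, was −0.79 without shHIRA I replicate 3, −0.21 without shLuciferase replicate 4, and −1.11 with the mitochondrial share as a covariate. In oxidative phosphorylation 9 of 48 genes fell and 2 rose, on either adjustment (median −0.14, camera adjusted p = 0.00641, fry adjusted p = 0.232, adjusted p = 0.864 with an estimated correlation). With shHIRA I the list was called (camera adjusted p = 0.000178, adjusted p = 0.674 with an estimated correlation), and in the libraries labelled shHIRA II it was not (0.254). Ndufs8 (−1.03), Ndufa4 (−1.10), Ndufs1 (−0.51) and Cox6b1 (−0.65), parts of the respiratory chain, fell. The share of mitochondrial mRNA was lower in the libraries labelled shHIRA II and not detectably with shHIRA I (two-sided exact permutation, adjusted p = 0.00646 and 0.105). Its means of 4.19% and 5.70% both lay under the control shRNA mean of 8.10%. The medians of oxidative phosphorylation were −0.08 and −0.15 in the same order. A call with only 1 hairpin therefore does not show that share and list part. The median of oxidative phosphorylation was −0.05 without shHIRA I replicate 2, which ended the call (adjusted p = 0.0816). It was −0.09 without shHIRA I replicate 1, −0.07 without shHIRA I replicate 4, −0.08 without shHIRA II replicate 4 and −0.37 without shHIRA I replicate 3. With the mitochondrial share as a covariate it was −0.57 with 29 falls, and without the 2 libraries of lowest share −0.42 with 33. Schwann cell and glial genes fell in 7 of 17 cases and rose in 2 (9 and 2 adjusted over the list alone, median −0.66, camera adjusted p = 0.0359, adjusted p = 0.435 with an estimated correlation): the myelin gene Mbp (−0.97) and the adhesion molecule Ncam1 (−0.95) fell, and Pmp22 rose (2.66). With neither hairpin alone was the list called (camera adjusted p = 0.0570 with shHIRA I and 0.0848 in the libraries labelled shHIRA II). The knockdown call ended without shHIRA I replicate 3 (adjusted p = 0.0649), shHIRA I replicate 4 (0.0707) or shLuciferase replicate 2 (0.0549), and with the mitochondrial covariate (median −0.11, adjusted p = 0.513).

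Genes of the extracellular matrix and mesenchyme were higher: 18 of 28 rose and 4 fell (19 and 6 adjusted over the list alone, median 0.93, camera adjusted p = 0.000202, adjusted p = 0.276 with an estimated correlation). The rise was carried by shHIRA I, where 21 rose and 1 fell (median 1.34). In the libraries labelled shHIRA II 9 rose and 7 fell and the list was not called (median 0.53, camera adjusted p = 0.254). Ctgf (2.68), the collagen chain Col5a1 (1.81) and the actin-binding Tagln (1.77) rose, and Fbln1 (−0.88) fell. Targets of TGF-beta and BMP rose in 9 of 17 cases and fell in 3 (13 and 4 adjusted over the list alone, median 0.72, camera adjusted p = 0.00577, adjusted p = 0.294 with an estimated correlation). Ctgf and Bambi (0.80) were higher and Pmepa1 lower (−1.45). Against parental cells this call ended (adjusted p = 0.308). All 4 called Notch targets of 8 rose, Hey1 (1.95), Hey2 (1.06), Dll1 (1.47) and Notch1 (0.75) (5 adjusted over the list alone, median 0.82, camera adjusted p = 0.00284, adjusted p = 0.0840 with an estimated correlation, and 0.0508 against parental cells). By hairpin the Notch list was called with shHIRA I (camera adjusted p = 0.000401, adjusted p = 0.0260 with an estimated correlation) and not in the libraries labelled shHIRA II (0.1196). Senescence and secretory genes rose in 9 of 17 cases and fell in 1, on either adjustment (median 0.56, camera adjusted p = 0.00606, adjusted p = 0.138 with an estimated correlation): Igfbp4 (1.90) and Csf1 (0.87) rose and the chemokine Ccl5 fell (−1.60). With the mitochondrial covariate that list was not called (median 0.37, adjusted p = 0.106). S phase genes rose in 8 of 45 cases and fell in none (3 adjusted over the list alone, median 0.42, camera adjusted p = 0.000361, fry adjusted p = 0.172, adjusted p = 0.864 with an estimated correlation). Among them were Ung (0.78), Cdca7 (0.86), Pola1 (1.10) and Gins2 (0.79). Their median was −0.18 against parental cells (adjusted p = 0.0512) and 0.05 with the mitochondrial covariate (adjusted p = 0.419).

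Other lists were not called as a whole by camera. In the HIRA complex and H3.3 list of 10, Hira and H3f3a (−0.40), a gene for H3.3 itself, fell and Asf1a (0.59), a chaperone that hands over H3, rose, as adjusted over the list alone too; the median was 0.06, the mean −0.01 and the test's direction down (adjusted p = 0.889). None of the 4 measured genes next to Hira was called by edgeR on either adjustment (camera adjusted p = 0.889). Of 35 replication-dependent histone genes Hist1h4i (0.89) and Hist1h1e (0.76) rose, and Hist2h2be (−1.17), Hist1h2bc (−1.11) and Hist1h2bg (−1.39) fell (1 and 2 adjusted over the list alone), with a median of 0.04, camera's direction up and fry's down (adjusted p = 0.924 and 0.887). Among 10 replication-independent histone genes H2afy (0.55) and H2afy2 (1.22) rose and H3f3a fell, on either adjustment (camera adjusted p = 0.724). G2 and M phase genes were called in 2 of 50 cases, Cks1b (0.70) and Gas2l3 (−0.68), and in none adjusted over the list alone (adjusted p = 0.629). The list was called lower with the mitochondrial covariate (median −0.41, adjusted p = 0.00496), against parental cells (−0.48, 5.14e-05) and without shLuciferase replicate 2 (−0.20, 0.0460). With an estimated correlation none of these calls held (adjusted p = 0.708, 0.578 and 0.873 in the same order). Targets of p53 rose in 5 and fell in 7 of 30 cases (6 and 7 adjusted over the list alone), Btg2 (2.55) and Trp53inp1 (−1.64), Xpc (−0.77) and Ccng1 (−0.72) among them; the median of −0.01, the mean of 0.04 and the test's direction down (adjusted p = 0.889) differed in sign, and the median turned positive with RLE or DESeq2 factors and with TPM. Neuronal genes Uchl1 (2.02) and Dcx (1.77) rose and Syp (−0.96) fell of 5 (4 and 1 adjusted over the list alone, camera adjusted p = 0.149, fry adjusted p = 0.00198). Epithelial genes Itgb4 (−1.89), Cdh1 (−1.69) and Esrp1 (−1.33) fell and Sfn (0.83) rose of 7, on either adjustment (camera adjusted p = 0.333, fry adjusted p = 0.00933), and of 6 leukocyte genes Cd68 (−0.71) fell, and none adjusted over the list alone (camera adjusted p = 0.889).

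The stress and signalling lists moved both ways. Amino acid stress and unfolded protein response genes rose in 9 and fell in 6 of 33 cases (12 and 6 adjusted over the list alone, camera adjusted p = 0.176). Atf3 (2.07) and Cebpb (1.23) were higher and Edem1 (−0.51) and Herpud1 (−0.64) lower. MAPK output genes rose in 6 and fell in 5 of 21 cases (7 and 5 adjusted over the list alone, camera adjusted p = 0.333). Junb (1.11) and Epha2 (1.35) were higher and Myc (−0.55) and Phlda1 (−0.59) lower. Wnt targets rose in 3 and fell in 3 of 13 cases (4 and 4 adjusted over the list alone, camera adjusted p = 0.724). Among them were Nkd1 (1.14), Bambi and Wif1 (−1.45). NRF2 targets rose in 6 and fell in 4 of 20 cases (8 and 5 adjusted over the list alone, camera adjusted p = 0.629). Among them were Osgin1 (0.82), Gstm1 (−0.97), Taldo1 (−0.36) and Prdx1 (−0.39). Glycolysis and hypoxia genes rose in 2 and fell in 8 of 28 cases, on either adjustment (camera adjusted p = 0.170, fry adjusted p = 0.0198). Ndrg1 (−1.66), Gpi1 (−0.67) and Egln1 (−0.63) were lower and P4ha1 (0.63) higher. Of 51 cytosolic ribosomal protein genes Rps2 (0.76) rose and 4 fell, among them Rpl30 (−0.52), Rpl17 (−0.39) and Rps16 (−0.31) (0 and 2 adjusted over the list alone, camera adjusted p = 0.333), with a median of −0.01 that turned positive with RLE or DESeq2 factors and with TPM. The list was called lower without the 2 libraries of lowest mitochondrial share (−0.23, 13 falls, adjusted p = 4.02e-05), without shHIRA I replicate 3 (−0.15, 0.00558) or shHIRA II replicate 2 (−0.10, 0.0382), with the share as a covariate (−0.34, 4.61e-06) and against parental cells (−0.28, 7.92e-05). With an estimated correlation all 5 calls were lost (adjusted p = 0.621, 0.779, 0.847, 0.556 and 0.548 in the same order).

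**Figure D3:**
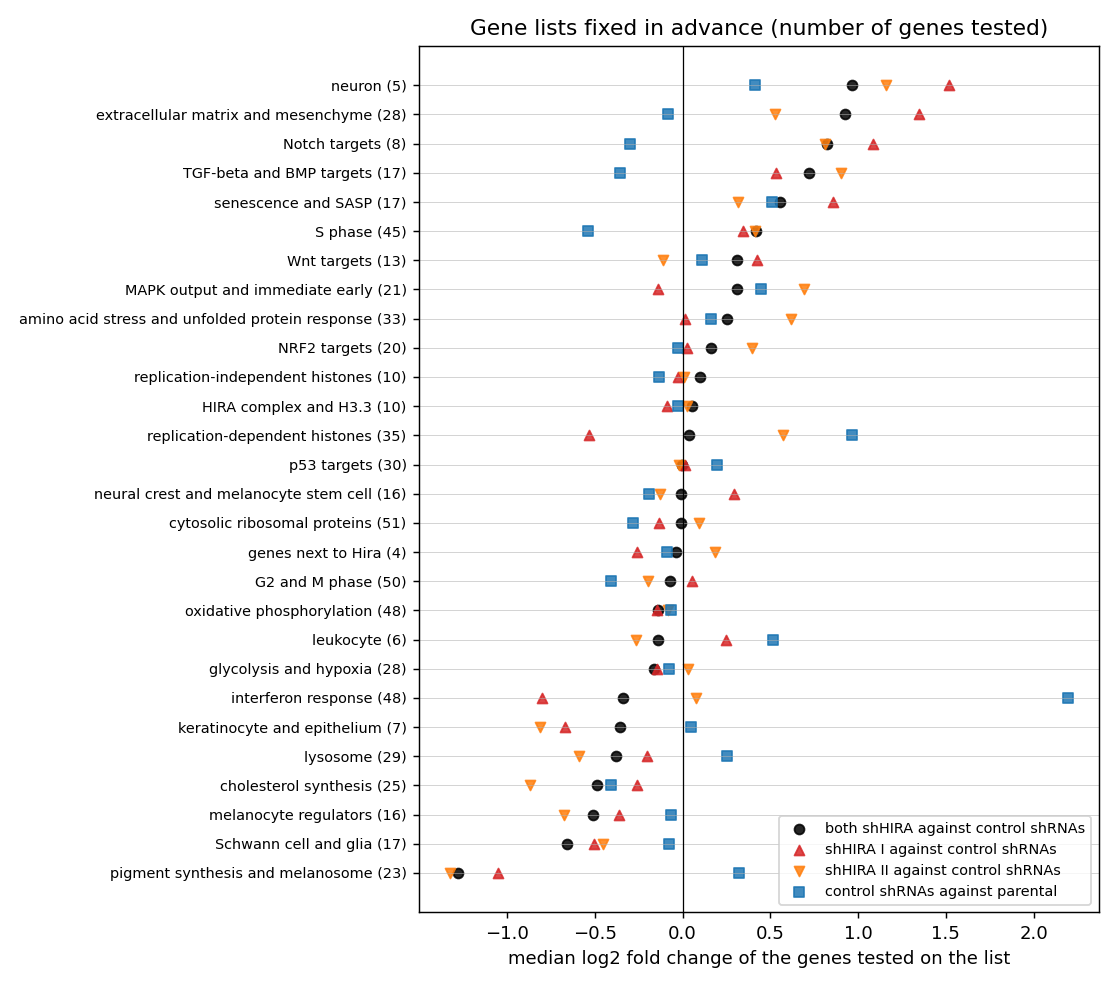
Median log2 fold change of each of the 28 gene lists with HIRA knockdown, with shHIRA I alone and in the libraries labelled shHIRA II, against the control shRNA libraries. Pigment synthesis and melanosome is lowest with knockdown at −1.28, and the matrix list stands at 1.34 with shHIRA I and 0.53 in the libraries labelled shHIRA II; neural crest, p53 target and ribosomal protein medians change sign with TPM.

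Among single genes called with both hairpins against both controls, the largest rises were those of Lamb1, a laminin chain (10.4-fold; log2 fold change 3.38, SE 0.51, adjusted p = 8.51e-05), and Aldh1a1, a retinaldehyde dehydrogenase (10.1-fold; 3.34, SE 0.34, adjusted p = 1.73e-06; chromosome 19, 20492715 to 20643465, plus strand). Aldh1a1 went from 1.57 ± 0.997 and 1.64 ± 0.662 CPM in the controls to 22.3 ± 5.53 CPM with shHIRA I and 11.9 ± 2.42 CPM in the libraries labelled shHIRA II (SD, n = 4 each). Its neighbour Aldh1a7 rose as well (3.13, adjusted p = 5.93e-07; chromosome 19, 20692953 to 20727562, minus strand), as did Cfap70 (3.27), Stmn4 (3.08), Stbd1 (2.97), Ctgf (2.68), Lhfp (2.54), the phosphatase Dusp8 (2.45), Il2rb (2.29) and P2rx7 (2.23). Btg2, an antiproliferative gene on chromosome 1 (134075170 to 134079120, minus strand), rose 5.86-fold (2.55, SE 0.19, adjusted p = 1.33e-07). The largest fall was that of Prb1, from 58.7 ± 41.1 and 88.3 ± 37.4 CPM to 0.960 ± 1.61 CPM with shHIRA I and 0.796 ± 0.667 CPM with shHIRA II. With shHIRA I 2 libraries were at 0, and 44.5% of its 31-mers occur in other genes, which leaves its level uncertain. Beside Tyr, Dct and Pmel, falls were led by the nuclear receptor Nr4a3 (−3.55, SE 0.31, adjusted p = 3.76e-07), Adck3 (−2.87), Sema6d (−2.71), the gap junction gene Gjb1 (−2.59), the lipase Mgll (−2.53), Pik3r3 (−2.51, 23.7% shared 31-mers), Abat (−2.35) and Nipal3 (−2.34). Against parental cells the rises of Aldh1a1 (1.94), Cfap70 (2.06) and Aldh1a7 (1.42) and the falls of Nr4a3 (−2.20), Adck3 (−1.88), Mgll (−1.40) and Pik3r3 (−1.64) were smaller, and that of Il2rb larger (4.19).

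In all, edgeR's quasi-likelihood test called 3964 of 13541 genes with knockdown, 1923 higher and 2041 lower; 690 of the rises and 441 of the falls exceeded 2-fold. On the TPM scale (limma on log2(TPM + 1)) 2594 genes rose and 1364 fell, 65.5% against 48.5% rising in the count test, so the balance of rises and falls was not the same under this other scale and test together. With RLE factors in the count test 50.5% rose. The count of genes changed by HIRA knockdown was 2610 in a fit that treats differences between hairpins as spread, 2289 with shLuciferase and 2628 with shScramble as the sole control, and 708 against a fold of 1.5.

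With shHIRA I, the hairpin that lowered Hira, matrix genes were higher as a group: 21 of 28 rose and 1 fell, on either adjustment (median 1.34, camera adjusted p = 7.87e-10, adjusted p = 0.0553 with an estimated correlation). Postn, a matricellular protein, went from 15.9 ± 16.2 and 11.9 ± 3.16 CPM to 199 ± 176 CPM (SD, n = 4 each; log2 fold change 3.86, SE 0.45, adjusted p = 1.38e-05), and Col5a1 (2.41), Loxl1 (1.97) and Mmp2 (1.34) rose. Pigment genes fell in 11 of 23 cases and rose in 1 (14 and 1 adjusted over the list alone, median −1.05, camera adjusted p = 1.39e-07, adjusted p = 0.253 with an estimated correlation). Dct (−2.51), Rab38 (−1.75), Rab27a (−1.51) and Tspan10 (−1.63) were lower. Interferon response genes fell in 15 of 48 cases (19 adjusted over the list alone, median −0.80, camera adjusted p = 3.5e-09, adjusted p = 0.546 with an estimated correlation). Among them were B2m (−1.18), H2-D1 (−1.35), Zbp1 (−2.63) and Cmpk2 (−1.89). Replicate 3 of shHIRA I ran the other way (mean log2 CPM of the members relative to all 20 libraries 0.812, against −0.447, −0.969 and −1.13 in replicates 1, 2 and 4). Without the 2 libraries of lowest mitochondrial share, left out after the data were seen, the median was −1.41 and 35 of 49 fell. The Notch targets Hey2 (1.78), Dll1 (1.90), Notch3 (1.60) and Dtx4 (0.83) rose of 8, on either adjustment (median 1.08, camera adjusted p = 0.000401), the one list still called with an estimated correlation (adjusted p = 0.0260). Oxidative phosphorylation genes fell in 10 of 48 cases and rose in 1 (11 and 1 adjusted over the list alone, camera adjusted p = 0.000178, adjusted p = 0.674 with an estimated correlation), in libraries whose mitochondrial mRNA share averaged 5.70%. Their median of −0.15 became −0.56 with 34 falls without the 2 libraries of lowest share, and −0.58 with 30 falls with the share as a covariate. Targets of TGF-beta and BMP rose in 7 and fell in 2 of 17 cases (8 and 2 adjusted over the list alone, camera adjusted p = 0.0155, 0.513 with an estimated correlation, and 0.0556 on the TPM scale, which ended the call).

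The largest single rises with shHIRA I were those of Clu, a secreted chaperone (2.56 ± 3.20 and 1.66 ± 1.01 to 55.0 ± 22.4 CPM, log2 fold change 4.72, SE 0.50, adjusted p = 4.76e-06), Clca2 (4.39, and 2.40 without shHIRA I replicate 2), Postn, Aldh1a1 (3.79) and Aldh1a7 (3.72). Prb1 (−6.20), Nr4a3 (−3.38), Tyr (−2.73), Adck3 (−2.66) and Lrrc24 (−2.63) fell most; 45.9% of the 31-mers of Lrrc24 lie antisense to another gene. Against parental cells Tyr was not called with shHIRA I (−0.25, adjusted p = 0.775). Mrpl40, next to Hira, fell by 0.49 (adjusted p = 0.0037). Genes changed by shHIRA I numbered 2671, 1470 higher (55.0%) and 1201 lower; on the TPM scale 1670 rose (66.8%) and 831 fell. With only the compared groups in the fit 1777 were called, and 609 against a fold of 1.5, 73.2% of them higher.

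In the libraries labelled shHIRA II, pigment and cholesterol synthesis genes were lower. Of 23 pigment genes 16 fell and 1 rose, on either adjustment (median −1.32, camera adjusted p = 3.21e-09, adjusted p = 0.305 with an estimated correlation). Tyr (−4.78), Pmel (−3.40), Slc24a5 (−2.94), Tspan10 (−2.71) and Rab27a (−2.42) were lower. Of 25 cholesterol synthesis genes 19 fell and none rose, on either adjustment (median −0.87, camera adjusted p = 7.65e-10, adjusted p = 0.305 with an estimated correlation). Among them were Insig1 (−1.92), Hmgcs1 (−1.34) and Dhcr7 (−0.99). Melanocyte regulators fell in 7 of 16 cases and rose in none, on either adjustment (median −0.67, camera adjusted p = 0.00333, adjusted p = 0.413 with an estimated correlation), with Kit at −2.37, Mitf at −1.90, Irf4 at −1.54 and Bhlhe40 at −1.23. With the mitochondrial covariate the median of regulators was −0.23. Lysosomal genes fell in 18 of 29 cases and rose in 1, on either adjustment (median −0.59, camera adjusted p = 8.08e-05, adjusted p = 0.518 with an estimated correlation). Among them were Lamp1 (−0.93), Asah1 (−1.02), Mcoln1 (−0.75) and Tpp1 (−1.24).

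Stress and growth factor response genes were higher in the same libraries. Amino acid stress and unfolded protein response genes rose in 17 of 33 cases and fell in 6 (19 and 7 adjusted over the list alone, median 0.62, camera adjusted p = 0.00493, adjusted p = 0.518 with an estimated correlation). Among them were Atf3 (2.23), Nupr1 (1.61) and Ppp1r15a (0.89). With the mitochondrial covariate 4 rose and 2 fell (median 0.25). MAPK output genes rose in 11 of 21 cases and fell in 3 (11 and 4 adjusted over the list alone, median 0.69, camera adjusted p = 0.0235, adjusted p = 0.518 with an estimated correlation). Etv4 (3.86), Junb (1.73), Epha2 (1.51) and Ier2 (1.33) were higher. NRF2 targets rose in 8 of 20 cases and fell in 3, on either adjustment (median 0.40, camera adjusted p = 0.0436, 0.518 with an estimated correlation, and 0.0548 on the TPM scale, which ended the call). Among them were Osgin1 (1.43), Pgd (0.76) and Hmox1 (0.75). Their median with the mitochondrial covariate was 0.11. The matrix list was not called here (9 rose and 7 fell of 28, median 0.53, camera adjusted p = 0.254): Ctgf (3.02) and Tagln (2.33) rose, and Dcn (−2.47) and Fbln1 (−1.54) fell. These libraries also held the lowest mean share of mitochondrial mRNA, 4.19%.

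By size of change, Maz (6.44), the nicotinic receptor subunit Chrnb2 (5.25), Lmbrd2 (4.97), Etv4 (from 4.56 ± 4.86 and 2.22 ± 2.23 to 46.2 ± 14.7 CPM) and Lamb1 (3.84) rose most in the libraries labelled shHIRA II. Maz, Chrnb2 and Lmbrd2 were at 0 in 2 or 3 of 4 libraries of every other group and lost their calls with DESeq2 (adjusted p = 0.0856, 0.0633 and 0.119). Maz also lost it with the mitochondrial covariate (0.115), without the 2 libraries of lowest mitochondrial share (0.0680) and without shHIRA II replicate 2 (4.54, adjusted p = 0.0892), and stood at 10.99 without shLuciferase replicate 3, as Lmbrd2 did at 8.07 without shLuciferase replicate 2. Prb1 (−6.47), Pck2 (−5.48, at 0 in 3 of 4 libraries, and −10.92 without shHIRA II replicate 3), Cxcl15 (−5.02), Tyr and Akap13 (−4.62, adjusted p = 0.033) fell most. The values 10.99, 8.07 and −10.92 come from fits that left a group all at 0, so their size is not an estimate. The call of Akap13 ended without shHIRA II replicate 1, 3 or 4 (adjusted p = 0.0908, 0.0829 and 0.0842), shLuciferase replicate 2 (0.0518) or shScramble replicate 2 (0.0552), and with the mitochondrial covariate (0.150). Genes changed by shHIRA II numbered 4394, 2132 higher (48.5%) and 2262 lower; on the TPM scale 2636 rose (61.5%) and 1649 fell. With the mitochondrial covariate 2767 were called, 2007 of them among the 4394, and 1201 were called against a fold of 1.5.

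To ask which changes the hairpins share, each was compared with each control. Both hairpins against both controls called 587 genes in 1 direction, 254 higher (43.3%) and 333 lower, Tyr, Dct, Pmel, Mgll and Aldh1a1 among them. For genes changed by both hairpins against both controls, 328 rose on the TPM scale (64.4%) and 181 fell, against a fold of 1.5 the count was 93, and it was 344 without shLuciferase replicate 3 and 382 without shLuciferase replicate 4. Across genes, which are not independent replicates, the log2 fold changes of shHIRA I and of the libraries labelled shHIRA II had Pearson's r = 0.50 (Spearman's rho 0.447) against the same 8 control libraries, where unchanged groups simulated against those controls gave 0.341 (SD 0.029). The covariance was 0.365 against a simulated 0.0544, a difference of 0.311. With split controls r was 0.383 and 0.378, against a simulated 0.00. Signs matched in 65.8% of genes, and in 60.7% of simulated ones. With split controls 341 genes rose and 395 fell with both hairpins, where independent lists of these sizes would share 94.5 and 105, and 318 rose and 441 fell in the other split, where they would share 113 and 130. In opposite directions moved 50 and 71 genes, against 202 and 248. Against parental cells r was 0.70 (simulated 0.50). The simulation held no effect of transduction. Both hairpin groups share that effect against parental cells, which can raise r without a shared effect of HIRA. Genes were simulated independently, so the simulated spread is too narrow for genes that vary together. Of 50 assignments of the real libraries to groups, 9 gave r of 0.501 or more, the real assignment included. Chance is therefore not excluded for the agreement.

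**Figure D4:**
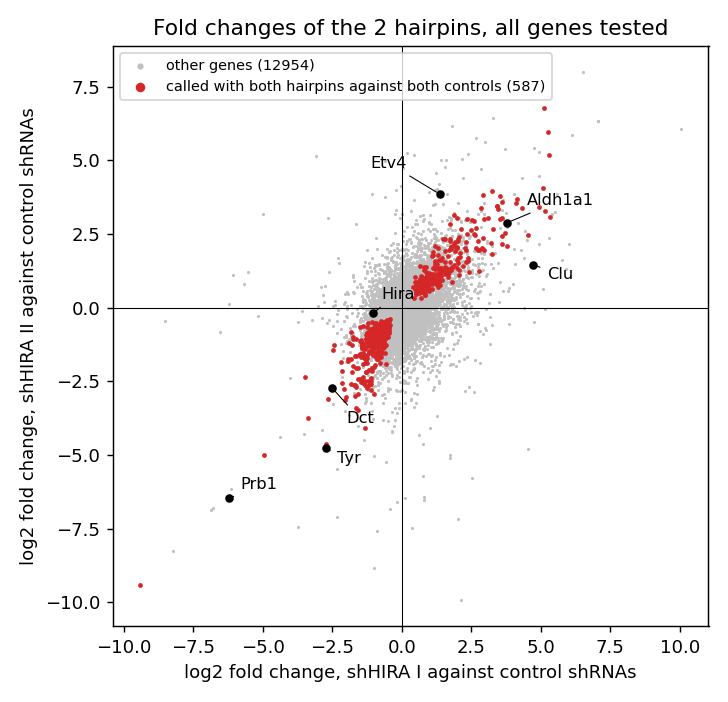
Log2 fold change of each tested gene with shHIRA I (horizontal) and in the libraries labelled shHIRA II (vertical) against the same 8 control shRNA libraries. Pearson's r is 0.50, and 616 genes rose and 640 fell with both hairpins. Unchanged groups simulated against these controls, with genes drawn independently, give 0.341. Of 50 assignments of the real libraries, 9 gave 0.501 or more, the real assignment included.

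A direct comparison of shHIRA II with shHIRA I tests whether the hairpins differ, and matrix and interferon genes did. Matrix genes were lower in the libraries labelled shHIRA II in 13 of 28 cases and higher in 1 (16 and 1 adjusted over the list alone, median −1.199, camera adjusted p = 1.48e-05, adjusted p = 0.390 with an estimated correlation). Among them were Dcn (−3.81), Col1a2 (−2.42), Loxl1 (−1.80) and Fbln1 (−1.33). Interferon response genes were higher in 9 of 48 cases and lower in 1, on either adjustment (median 0.90, camera adjusted p = 2.61e-08, adjusted p = 0.415 with an estimated correlation). Among them were Zbp1 (3.85), Mx2 (2.31), Cxcl10 (1.90) and H2-D1 (1.17). Without the 2 libraries of lowest mitochondrial share the median was 1.40, with 31 higher and 1 lower. Replication-dependent histone genes were higher in 9 of 35 cases, on either adjustment (median 0.86, camera adjusted p = 1.48e-05, adjusted p = 0.390 with an estimated correlation). Among them were Hist1h1e (1.51), Hist1h3b (1.69), Hist1h3i (2.35) and Hist1h4d (1.49). Cholesterol synthesis genes were lower in 9 of 25 cases (10 adjusted over the list alone, median −0.49, camera adjusted p = 2.27e-06, adjusted p = 0.4 with an estimated correlation). Insig1 (−1.34), Dhcr7 (−1.30), Hmgcs1 (−1.28) and Cyp51 (−1.22) were among them. Melanocyte regulators were lower in 8 of 16 cases and higher in 1, on either adjustment (median −0.87, camera adjusted p = 0.0135, adjusted p = 0.401 with an estimated correlation). Mitf (−1.37), Tfap2a (−1.23) and Bcl2 (−1.17) were lower and Tfe3 (0.65) higher. The median of regulators was −0.34 with the mitochondrial covariate.

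Car6 (5.41 ± 3.83 with shHIRA I, 50.5 ± 8.53 CPM with shHIRA II; 3.22, SE 0.36, adjusted p = 1.83e-05), Angptl6 (2.79) and Fam136a (2.50, SE 0.17, adjusted p = 7.33e-08) were higher in the libraries labelled shHIRA II, as were Lmbrd2 (5.58) and Chrnb2 (5.06). Fam136a stood at 42.4 ± 7.32 and 45 ± 4.92 CPM with the control hairpins, 11.2 ± 2.19 CPM with shHIRA I and 63.8 ± 8.92 CPM with shHIRA II. Akap13 (−5.38), Igfbp5 (−5.11), Ly6c1 (−4.58), Clca2 (−4.39) and C1s1 (123 ± 102 to 5.85 ± 1.20 CPM; −4.39) were lower, of which Ly6c1 shares 46.8% and C1s1 33.5% of its 31-mers with other genes. Without shHIRA I replicate 2, Ly6c1 was not called (−2.37, adjusted p = 0.0902), Clca2 stood at −2.41, Lmbrd2 at 11.21 and Akap13 and Chrnb2 were not called (adjusted p = 0.0729 and 0.0707). Akap13 also lost its call without shHIRA II replicate 1, 3 or 4 (0.0827, 0.0751 and 0.0794), Chrnb2 without shHIRA I replicate 1 (0.0608) or shHIRA II replicate 1 or 4 (0.0694 and 0.0506), with 11.33 without shHIRA I replicate 4, and Lmbrd2 without shHIRA I replicate 4 (0.0618) or shHIRA II replicate 1 (0.0525). The values 11.21 and 11.33 come from fits whose remaining shHIRA I libraries were all at 0, so their size is not an estimate. DESeq2 called neither Lmbrd2 nor Chrnb2 here (0.163 and 0.156). Genes differing between the hairpins numbered 2845, 1164 higher (40.9%) and 1681 lower in the libraries labelled shHIRA II; the count was 4430 without shHIRA I replicate 3, 1088 with only these groups in the fit and 623 against a fold of 1.5.

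The control hairpins differed in no gene under the main test and in few under others. The main edgeR fit called 0 genes between shScramble and shLuciferase, with 170 at an unadjusted p under 0.05. From limma came 0 calls and from DESeq2 4 (187 at an unadjusted p under 0.05). The 4 genes that DESeq2 called were Gm10925, Gm28439, Gm28661 and Hmgn2-ps1, predicted genes or pseudogenes named after their values were seen. Gm28661 was also called by edgeR with only these groups in the fit (adjusted p = 0.00697), without parental replicate 1 (0.0422) and without parental replicate 4 (0.0473). Camera with its preset correlation called 6 of the 28 lists here, oxidative phosphorylation foremost (median 0.19, adjusted p = 6.03e-11), although no member was called; with an estimated correlation the lowest adjusted p was 0.647 and fry called 0 lists.

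Transduction with a control hairpin raised interferon response genes above parental cells: 38 of 48 rose and none fell (44 adjusted over the list alone, median 2.19, camera adjusted p = 8.26e-41, fry adjusted p = 0.00321, adjusted p = 0.0976 with an estimated correlation). Usp18, a brake on interferon signalling, went from 1.25 ± 0.188 CPM in parental cells to 59.8 ± 44.2 and 70.7 ± 41.5 CPM with shLuciferase and shScramble (SD, n = 4 each; log2 fold change 5.69, SE 1.07, adjusted p = 0.00553), and Gbp7 (3.24), Ifih1 (2.66), Ddx58 (2.49) and Parp14 (2.37), the middle pair being cytosolic RNA sensors, rose with it. Replication-dependent histone genes rose in 10 of 35 cases (15, and 1 lower, adjusted over the list alone, median 0.96, camera adjusted p = 6.08e-08, adjusted p = 0.0976 with an estimated correlation). Among them were Hist1h4j (2.56), Hist1h1c (2.29) and Hist1h2bc (1.95). Of 45 S phase genes 5 fell, among them Cdca7 (−1.18), Ung (−0.85), Rfc2 (−0.73) and Rrm1 (−0.66) (12 adjusted over the list alone, median −0.54, camera adjusted p = 2.2e-15, adjusted p = 0.284 with an estimated correlation). Stress genes rose in 7 of 33 cases (9 adjusted over the list alone, median 0.16, camera adjusted p = 0.000198, adjusted p = 0.284 with an estimated correlation). Atf3 (3.49), Chac1 (2.69), Nupr1 (1.77) and Ddit3 (1.25) were among them. The mitochondrial covariate moved the median to 0.29, with 10 higher. The pigment genes Tyr (2.48), Myrip (2.01) and Hps4 (0.58) rose of 23 (5, and 2 lower, adjusted over the list alone, median 0.32, camera adjusted p = 0.0120, adjusted p = 0.462 with an estimated correlation), and 3 of 25 cholesterol genes fell, among them Cyp51 (−0.63) and Sqle (−0.44) (12 adjusted over the list alone, median −0.41, camera adjusted p = 1.56e-08, adjusted p = 0.196 with an estimated correlation).

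The largest rises with transduction were those of Oas1a (6.63, adjusted p = 0.0196), Oas1g (6.51), Usp18, Oas2 (5.04) and Apol9a (5.01). The largest falls were those of Colq (−1.93), Enpp1 (−1.81), Myb (−1.78; 82.4 ± 43.6 to 22.6 ± 5.25 and 25.5 ± 3.42 CPM), Mnd1 (−1.62) and Rfng (−1.54). Sequence shared with other genes leaves Oas1a (68.8%), Oas1g (55.1%), Mnd1 (56.5%) and Apol9a (20.3%) uncertain. Oas1a lost its call without any of parental replicates 1 to 4 (adjusted p = 0.0714, 0.0779, 0.0718 and 0.0526), and Myb without parental replicate 2 (0.0520). Genes changed by control transduction numbered 490, 278 higher (56.7%) and 212 lower; on the TPM scale 231 rose (73.1%) and 85 fell. The count moved with the libraries: 238, 214, 216 and 258 without parental replicates 1 to 4, 300 and 296 without shLuciferase replicates 3 and 4, 320 and 311 without shScramble replicates 2 and 3, and 791 without shHIRA I replicate 3. DESeq2 called 868 genes, a fit of only these groups 880 and the fit with the mitochondrial covariate 798.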

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

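Several comparisons were chosen only after the results were seen. They were those of the libraries labelled shHIRA II with effects of that hairpin alone and with wrongly labelled control libraries. The others were those of pigment genes with parental cells and of matrix genes with fibroblast genes, by either test.

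The hairpins differed in 12 of 25 genes named for the knockdown, in a test of the difference itself (shHIRA II minus shHIRA I, edgeR, adjusted over all genes). Hira (0.86) and Il2rb (1.13) stood higher in the libraries labelled shHIRA II. Lower there were Aldh1a7 (−1.18), Btg2 (−1.42), Dusp8 (−0.999), Tyr (−2.04), Sema6d (−2.76), Gjb1 (−1.07), Mgll (−1.02), Pmel (−1.75), Pik3r3 (−1.90) and Nipal3 (−1.28). Of 28 lists, 8 differed by both camera and fry. Median differences were −0.868 for melanocyte regulators, 0.862 for replication-dependent histones, 0.904 for the interferon response, −1.199 for extracellular matrix and mesenchyme, −0.494 for cholesterol synthesis, 0.450 for amino acid stress and unfolded protein response, 0.474 for MAPK output and 0.595 for NRF2 targets. None of these lists passed with an estimated correlation, where the lowest adjusted p was 0.390.

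A single library lay far from the other 3 of its group in 21 of 270 groups tested, by the gap to its nearest neighbour as a share of the group's range. Chance alone picks about 1 in 20 groups, or 13.5 here. In the share of mitochondrial mRNA it was shHIRA II replicate 2, at 2.88% (gap share 0.857). In log2 CPM the highest library stood apart for Ctgf in shScramble replicate 1 (0.861), Btg2 (0.890), Lhfp (0.870) and Postn (0.885) in shLuciferase replicate 2, and Nr4a3 in parental replicate 4 (0.896). The lowest stood apart for Mgll (0.832), Pik3r3 (0.874) and Cxcl15 (0.879) in shScramble replicate 1 and Pck2 in shLuciferase replicate 1 (0.919). The gap share was 1 where 3 of 4 libraries held a 0: Maz in parental replicate 4, shLuciferase replicate 3, shScramble replicate 4 and shHIRA I replicate 2, Chrnb2 in parental replicate 1 and shHIRA I replicate 4, Lmbrd2 in parental replicate 4, shLuciferase replicate 2 and shHIRA I replicate 2, and Pck2 in shHIRA II replicate 3. It was also 1 for Ly6c1 in parental replicate 4.

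Other assignments of the libraries to groups show what chance could give. For HIRA knockdown 3964 genes were called and at most 1372 in the others of 50 assignments drawn, so that 1 reached the real count, the real one itself. The same value of 1 held for both hairpins against both controls (587, highest other 0), shHIRA I (2671, highest other 1424, 60 assignments) and the libraries labelled shHIRA II (4394, highest other 982). It also held for transduction (490, highest other 0) and the hairpins' difference (2845, highest other 2330, 35 assignments). These counts argue against chance but do not exclude it, since at most 60 assignments were drawn for each. For the lists 8 of 50 assignments called 12 or more (highest other 14), and for the agreement of the hairpins 9 of 50 gave r of 0.501 or more (highest other 0.655), so chance cannot be excluded for either. Between the control hairpins all 35 assignments gave 0 genes.

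The libraries labelled shHIRA II differed from the control shRNA libraries in 4394 genes although Hira was not measurably lower there (87.8% of control, interval 72.0 to 107%). Effects of this hairpin alone would leave few genes shared with shHIRA I, and 587 were called in 1 direction with both hairpins against both controls. The highest other assignment gave 0, but these assignments break up the hairpin groups and so do not bear on this explanation. With split controls 736 and 759 genes were shared, where independent lists would share 200 and 243. That expectation takes genes as independent, so the excess argues against the explanation for the shared part only and does not exclude it. A lower mitochondrial share may account for part of the 4394 genes: with it as a covariate 2767 genes were called, but 2387 of the 4394 were not and 2007 were. At most 330 were called with the covariate in the 59 other assignments drawn. These mix shHIRA II with control libraries, so they do not bear on this explanation either. The 2007 genes that kept their call argue against the share as the whole cause, only so far as the covariate's slope holds. The covariate's slope comes from spread within groups, widest with shHIRA I (SD 3.44%, against 0.876 to 1.51% in the others). Such fits, here and below, assume that this slope holds in every group. Control shRNA libraries under a wrong label would differ from the controls about as little as the control hairpins did from each other (0 genes), so other wrong labels, HIRA loss at the protein level and effects of both hairpins on other targets stay open, none of them tested.

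Pigment genes were lower in the shHIRA libraries. Higher pigment genes in the control shRNA libraries would leave no fall against parental cells, but the list's median there was −0.965 over both hairpins together. This value does not speak for each hairpin or library singly. A lower mitochondrial share could lower the pigment genes, yet with it as a covariate the median was −1.09, under the assumption given above. Admixed cells without pigment cannot be told apart from a change in the cells: 60.9% of the members lay more than 3 SE from the list's median, past the bound set beforehand, but that bound assumed cells lacking every member, which no table measures. Among the members, Tyr did not differ detectably from parental cells with shHIRA I (−0.25, adjusted p = 0.775), so its fall there may rest on its rise with transduction. The other members were also compared with parental cells for each hairpin, and those values are not reported here.

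Matrix genes were higher in the shHIRA I libraries. Admixed fibroblasts would bring in abundant fibroblast genes, and 3 of 4 rose: Col1a1 to 18.8 CPM, Col1a2 to 67.9 CPM and Dcn to 73.1 CPM, with Col3a1 at 0.537 CPM. Of 11 tested fibroblast genes 6 rose and 1 (Fap) fell, and 7 of the 17 genes looked at stand on the matrix list too, so this count decides nothing. Col3a1, Col6a1 and Col6a2, also abundant in fibroblasts, reached at most 3.27% (mean plus 2 SD) of the mean rise of Col1a2 and Dcn of 43.3 CPM, which argues against fibroblasts as the cause of the whole rise. A lower mitochondrial share was argued against by a median of 1.58 with that covariate, only so far as its slope, set largely within shHIRA I, holds. A small admixture behind part of the rise, or a change in the cells themselves, stays open.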

How the results depend on the processing

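The share of mitochondrial mRNA as a covariate, the fit without the 2 libraries of lowest share and the sum of Hira and Gm28539 were chosen after seeing the data. Against a fold of 1.5, which asks for larger changes, 708 genes passed for HIRA knockdown, 609 for shHIRA I, 1201 for the libraries labelled shHIRA II, 93 for both hairpins against both controls, 623 between the hairpins and 75 for transduction, and Hira pooled over hairpins did not pass (−0.62, adjusted p = 0.82). With only the compared groups in the fit, 1777 genes passed for shHIRA I and 1088 between the hairpins. In such fits 1 passed between the controls and 880 for transduction. The main fit gave 2671, 2845, 0 and 490 in the same order. Counts moved both ways, so fewer libraries alone do not account for them. The main fit shares 1 spread per gene over all groups, so a group of wider spread enters every comparison. The part this plays was not tested. For HIRA knockdown the 2-group fit gave 2610 genes and Hira at −0.53 (adjusted p = 0.0511), and shLuciferase or shScramble alone gave 2289 and 2628. DESeq2 gave 4 genes between the controls and 868 for transduction, and limma on log2(TPM + 1) 316 for transduction. With the mitochondrial covariate 2767 genes passed in the libraries labelled shHIRA II and 798 for transduction, Hira with shHIRA II passed (−0.46, adjusted p = 0.0394) and the agreement was 0.576. Without the 2 libraries of lowest share the count for transduction was 844 and the agreement 0.397. Split controls gave an agreement of 0.383 and 0.378 and parental controls 0.698. With an estimated correlation 0 lists passed for HIRA knockdown. With parental controls S phase turned to −0.18 (adjusted p = 0.0512) and the interferon response to 1.74 (adjusted p = 2.9e-12, and 0.345 with an estimated correlation). Where no stricter threshold is named, the cause was not tested.

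Leaving out each library in turn gave 3331 to 4681 genes for HIRA knockdown, 2210 to 3140 for shHIRA I, 3253 to 5379 for the libraries labelled shHIRA II, 344 to 837 for both hairpins against both controls, 1997 to 4430 between the hairpins, 0 to 1 between the controls and 214 to 791 for transduction. Hira ran from −0.67 to −0.56 pooled, −1.17 to −0.92 with shHIRA I and −0.25 to −0.14 with shHIRA II, the lists from 11 to 13 and the agreement from 0.385 to 0.534. Single genes kept their call and direction in 800 alternative results and lost it in 26, and in 1278 and 22 with a library left out. The 12 lists called for HIRA knockdown kept call and direction in 59 alternative results, lost the call in 23 and turned in 2, and in 188, 4 and 0 with a library left out. The 16 others stayed uncalled in 100 and gained a call in 12, and in 252 and 4 with a library left out. Depth of at most 20.7 M counts (M, 1e6) per library limits what can be said of genes near 0 counts.

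Replicate numbers are not known to pair libraries. Over 40 pairs of libraries with the same number, correlations ran from −0.29 to 0.39, 12 were over 0.1, and 13 of 20 libraries correlated best with their own number. The mean was 0.0586 for these pairs and −0.0195 for pairs with other numbers. A batch shared by number is therefore possible, and the main fit does not model it. With the number as a block, 4354 genes passed for HIRA knockdown, 2958 for shHIRA I, 4806 for the libraries labelled shHIRA II, 753 for both hairpins against both controls, 3147 between the hairpins, 0 between the controls and 607 for transduction, with 12 lists and an agreement of 0.504. The block, for the agreement added after seeing the data, changed no call of Hira.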

Other observations

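Against parental cells replication-dependent histone genes stood higher in the shHIRA libraries (median 1.17, camera adjusted p = 0.000145, adjusted p = 0.278 with an estimated correlation), as they did in the control shRNA libraries (10 of 35 rose, median 0.96). Cholesterol synthesis genes were lower than in parental cells by a median of 0.884 (camera adjusted p = 1.21e-14, adjusted p = 0.0968 with an estimated correlation). The interferon gene Usp18 was uneven among transduced libraries, at 43.5 ± 70.5 CPM with shHIRA I and 119 ± 54.4 CPM in the libraries labelled shHIRA II (SD, n = 4 each), and at 1.25 ± 0.188 CPM in parental cells. Car6 stood at 13.8 ± 4.64 CPM in parental cells, 5.41 ± 3.83 CPM with shHIRA I and 50.5 ± 8.53 CPM in the libraries labelled shHIRA II.

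The first 3 components of a principal component analysis of log2 CPM held 25.0, 12.2 and 11.9% of the variance. The share of mitochondrial mRNA did not differ detectably between control shRNA and parental libraries (two-sided exact permutation p = 0.259, adjusted 0.318). With the share as a covariate, a fit chosen after the data were seen, 2995 genes were called for HIRA knockdown, 2035 of them among the 3964.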
